A study of Mus musculus with 4 samples.

How the data were processed

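The samples were 4 ATAC-seq libraries of sorted mouse cells, 2 of cochlear hair cells at postnatal day 1 and 2 of cerebellar granule neuron progenitors at postnatal day 7, each from 500 cells. Groups and replicate numbers came from the labels. Per the submitters' processing notes, the tools named were fastp 0.21.0, Bowtie2 2.4.4, SAMtools 1.12, Picard, MACS2 2.2.7.1, bedtools 2.30.0 and deepTools, and the build was mm10. Their options, read filters and any shift of reads for the transposase offset were not given in the sources used here, nor were read totals. The authors deposited 1 MACS2 list of narrow peaks per library, so peaks had been called per library and not on pooled reads. Per the file layout, each deposited line gives a position, a score, the fold enrichment at the summit over the local background, the -log10 p and -log10 q values, and the summit. The lowest -log10 q of a list ranged from 2.00 to 2.02, which places the authors' threshold near 2 in every list. The fold enrichment and -log10 values are the authors' and were used only to describe, rank or filter peaks within a list. The deposited score column was not used.

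Peaks on chromosomes 1 to 19, X and Y were used, and 14 and 10 peaks of hair cell replicates 1 and 2 on other sequences were set aside. No position occurred more than once in a list, and no 2 lists were identical. In MACS2 the fold is the pileup plus 1 over the background plus 1, and the p-value is the Poisson tail of the pileup, so both values together give the whole-number summit pileup and the local background. This worked for 100% of peaks in each list, within a relative tolerance of 1e-04. The lowest background of a list, its genome-wide level, was taken as a measure of relative depth. It depends on fragment extension as well as on reads.

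Peaks of all lists that overlapped by at least 1 bp were merged into regions. A region was hair cell-specific with a peak in both hair cell libraries and neither progenitor library, progenitor-specific in the opposite case, and shared with a peak in all 4. Absence means that no peak was called. A specific region counted as high enough for the other group's depth when its smaller height over background, scaled to each library of the other group, exceeded the weakest 10% of the pileups called there, 4 fragments in each progenitor library and 8 in each hair cell library. All 4346 progenitor-specific regions met this, because scaling to the deeper libraries raises their heights. In a version that applies 1 cut to both classes, the smaller height in the own group had to exceed 38.5 times the background. This was the highest of the 4 libraries' weakest 10%, that of progenitor replicate 1, so most progenitor-specific regions passed it.

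Gene coordinates came from a RefSeq gene table of the same build (21887 protein-coding genes). It gives no strand, and no genome sequence was used here. The plan had been to use transcription start sites. In their place, gene ends (1 kb either side of the start or end coordinate) stood for promoters, and a region was assigned to the gene whose body held its centre, otherwise to the gene with the nearest end within 100 kb. A gene-end peak of a library is a merged region with a peak in that library that overlaps a gene end. The peak of another library can carry such a region to the gene end. The planned motif counts needed sequence and were not run. Of all regions 22.5% lay at a gene end, against 5.83% after a shift of 50 kb, a check that both use the same coordinates.

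The 20 gene lists were fixed before the data were examined, as were the tests, the definitions of specific regions and the rule for named genes. They cover hair cell transcription factors, hair cell function, Notch ligands, supporting cells, otic patterning, epithelium, granule neuron progenitor identity, the Sonic hedgehog pathway, granule neuron maturation, pan-neuronal genes, Purkinje cells, other cerebellar neurons, glia, spiral ganglion, mesenchyme, immune, erythroid and endothelial cells, the cell cycle and housekeeping. They hold 321 entries and 319 distinct genes, 2 of them on more than 1 list, and all were found by symbol. For each list the mean over genes of hair cell-specific minus progenitor-specific regions was set against 100000 random lists of protein-coding genes matched on the number of group-specific regions (two-sided permutation test, Benjamini-Hochberg adjustment over the 20 lists). The named genes were Atoh1, the 12 genes with the largest excess in each direction (ties by the number of regions in that direction, then by the median rank of their fold enrichment, then by symbol), and up to 4 genes per list with the largest absolute excess. Some genes that this rule takes are not reported here. The named regions were the 5 of each class with the highest lower rank of fold enrichment over its libraries.

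Agreement of libraries was tested with an exact permutation test of the base-pair Jaccard index, and shares of regions with Fisher's exact test and exact (Clopper-Pearson) 95% intervals. Alternatives were a -log10 q of at least 5, equal numbers of peaks from every list (those with the highest -log10 p), a reciprocal overlap of 50%, summits within 250 bp, chromosomes 1 to 19 only, each library left out in turn, only regions high enough for the other group's depth, a distance limit of 25 kb, unmatched random lists, regions outside gene ends, and a gene end window of 2.5 kb. Assignment by the nearest end of any gene, 1 height over background asked of both classes, a Jaccard index of regions, libraries left out of the agreement test, high-enough regions for lists and gene ends, shares in gene bodies and beyond 100 kb, and all alternatives at the Atoh1 locus were added after seeing the data.

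The steps were tested on simulated data. Pileups were recovered for 100% of 11811 simulated peaks and classes for 100% of 6000 simulated regions. The pileups were simulated with the formulas used to recover them, and the regions were well separated. Both results therefore check the code only and not its accuracy on real peaks. With region counts simulated for the 21887 genes, 3.5% of 200 random lists of 20 genes passed the permutation test at 0.05, and 94% of 200 lists did after 1 hair cell-specific region per gene was added on average and most progenitor-specific ones removed. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.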

Results

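Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in 2 sorted mouse cell populations. The first was cochlear hair cells, the mechanosensory cells of the inner ear, at postnatal day 1. The other was cerebellar granule neuron progenitors, the dividing precursors of granule neurons, at postnatal day 7. Both were sorted from mice that carry a tagged Atoh1 allele with a tdTomato reporter, and Atoh1 encodes a basic helix-loop-helix transcription factor that both cell types depend on. Each group had 2 libraries of 500 cells, and the data are 1 list of peaks per library. The labels do not say whether the libraries of a group came from separate animals or sorts, so any spread between them may be technical. The hair cell lists held 30523 and 34966 peaks in replicates 1 and 2, and the progenitor lists held 14528 and 21332. On chromosomes 1 to 19, X and Y the peaks covered 13.7 and 15.1 Mb in hair cells and 4.78 and 7.83 Mb in progenitors. Read totals were not used here, but the caller's values give the background pileup behind each list, which scales with depth and fragment length. It was 0.552 and 0.441 fragments in the hair cell libraries and 0.104 and 0.141 in the progenitor libraries, a mean ratio of 4.06. Peaks were therefore called from more signal in hair cells, with a median summit pileup of 15 fragments in both libraries against 8 and 9 in progenitors.

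Libraries of the same cell type shared more open bases than libraries of different cell types. The Jaccard index, shared bases over all covered bases, was 0.509 between the hair cell libraries and 0.301 between the progenitor libraries. Between cell types it ranged from 0.116 to 0.167, with a mean of 0.142 ± 0.0270 (SD, n = 4 pairs of libraries). The mean within groups exceeded the mean between groups by 0.263, and the higher of the other splits gave -0.131. An exact permutation test, one-sided, has only 3 splits for 4 libraries, so p = 0.333 is the smallest value it allows and no threshold can be passed.

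Hair cells and progenitors each had regions open in both of their own libraries and in neither library of the other cell type. Peaks of all lists that overlapped by at least 1 bp merged into 56032 regions, of which 14952 were hair cell-specific, 4346 progenitor-specific and 5048 open in all 4 libraries. The strongest hair cell-specific region by rank in both lists lay on chromosome 16 at 78089085 to 78089593 (mm10), over 100 kb from any protein-coding gene, with fold enrichments of 18.3 and 21.8. The next were inside the glypican gene Gpc5 (chromosome 14, 116473401 to 116473908), on chromosome 6 at 81760218 to 81760707, 8706 bp from an end of the cerebellin gene Cbln1 (chromosome 8, 87459872 to 87460423), and nearest to the calcium channel gene Cacna2d1 (chromosome 5, 15850252 to 15850793). The strongest progenitor-specific region overlapped an end of Stmn2, which encodes a neuronal regulator of microtubules (chromosome 3, 8561407 to 8562251), with fold enrichments of 13.6 in both libraries. The others of the top 5 lay 12444 bp from Adgrf1 (chromosome 17, 43257601 to 43258079) or over 100 kb from a gene, on chromosome 4 at 71517843 to 71518325, chromosome 16 at 86694427 to 86694919 and chromosome 3 at 50014362 to 50014787. The 5 strongest shared regions were all at gene ends, those of Hsd17b12, Ift57, Anapc4, Tsks and Hjurp.

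Hair cell-specific regions outnumbered progenitor-specific ones 3.44 to 1 with the peaks as listed. Regions open in 1 library of each cell type and absent from the remaining pair numbered 118 to 573 per combination. These counts are no measure of chance for the specific regions, since depth followed the cell type. A mixed pattern needs a deeper hair cell library to lack the peak, and a hair cell-specific pattern does not. Of the regions found in both hair cell libraries 62.5% were hair cell-specific, and of those in both progenitor libraries 43.3% were progenitor-specific. With 2 against 2 libraries an exact permutation test has only the 3 splits named above, with a smallest p = 0.333, so no region or count could pass a threshold. The ratio depended on which peaks were used. It was 5.77 with peaks of -log10 q of at least 5 and 1.29 with the same number of peaks taken from every list. Among regions high enough over background to be called at the other group's depth it was 0.809, with 3517 hair cell-specific and 4346 progenitor-specific regions, but that filter could remove hair cell-specific regions only. With 1 height over background asked of both classes it was 0.888, with 3517 and 3961 regions. That height was set by the weakest 10% of progenitor replicate 1, so it too removed mostly hair cell-specific regions. Without granule neuron progenitor replicate 1 the ratio was 1.36, and without hair cell replicate 1 it was 5.38. A further 25890 regions, 46.2% of all, had a peak in a single library.

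**Figure D1:**
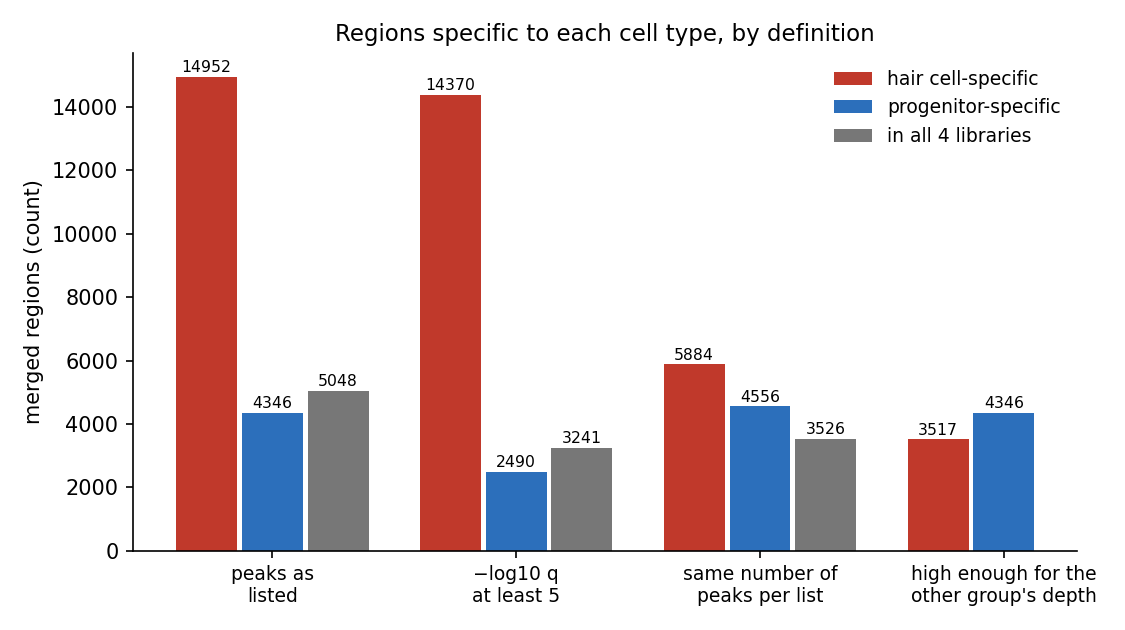
Merged regions (count, vertical axis) that were hair cell-specific, progenitor-specific or open in all 4 libraries, with the peaks as listed, with a stricter q, with equal numbers of peaks per list, and with only the regions high enough for the other group's depth (a class that regions open in all 4 libraries do not enter). Hair cell-specific regions went from 14952 to 3517 across these definitions, and progenitor-specific regions were at 4346 in both the first and the last.

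The study concerned enhancers of Atoh1, and around this gene (chromosome 6, 64729125 to 64731245) hair cells had 2 open regions that the progenitor lists lacked. They lay 70.5 kb and 94.3 kb beyond the start coordinate of Atoh1, at 64799368 to 64799946 and 64823147 to 64823747, between genes in the annotation. Their fold enrichments in hair cell replicates 1 and 2 were 12.4 and 13.5 for the nearer region and 11.6 and 13.1 for the farther one, which placed both between the percentiles 90.7 and 93.7 of their lists. A region 3.31 kb past the end coordinate of Atoh1 (64734140 to 64735010) was open in all 4 libraries, with fold enrichments of 11.6 and 11.5 in hair cells and 4.89 and 7.13 in progenitors. The region at the start of the gene (64728660 to 64729384), which also touches the end of the long noncoding RNA gene Gm35851, had a peak in both hair cell libraries and in progenitor replicate 2. A region 1.23 kb before the start coordinate (64727730 to 64728208), inside Gm35851, had a peak in both hair cell libraries and in progenitor replicate 1. The other peaks within 100 kb were seen in a single library each, 2 in hair cell replicate 1 and 1 in progenitor replicate 2.

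Scaled to the background of progenitor replicates 1 and 2, the nearer hair cell-specific region would have had a pileup of 6.78 and 9.18 fragments and the farther one 5.65 and 7.65. The weakest 10% of progenitor peaks had pileups of up to 4, but regions of such heights were often missed. The region at the start of Atoh1, at 7.72 by the same scaling, had no peak in progenitor replicate 1, and the region 1.23 kb before the start coordinate, at 6.12, had none in replicate 2. Of the regions outside gene ends in 1 progenitor library whose height over background was within a factor of 1.2 of the nearer region's, 47.1% were found again in replicate 1 and 67.2% in replicate 2. For the farther region these shares were 38.7% and 52.7%. The lack of a progenitor peak at the 2 regions therefore does not show that they were closed. No progenitor-specific region was found within 100 kb of Atoh1 with all 4 libraries. Without granule neuron progenitor replicate 1 there were 3 hair cell-specific regions and 1 progenitor-specific region. Without hair cell replicate 2 the count of hair cell-specific regions there rose from 2 to 4, since the peaks seen in replicate 1 alone then counted.

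**Figure D2:**
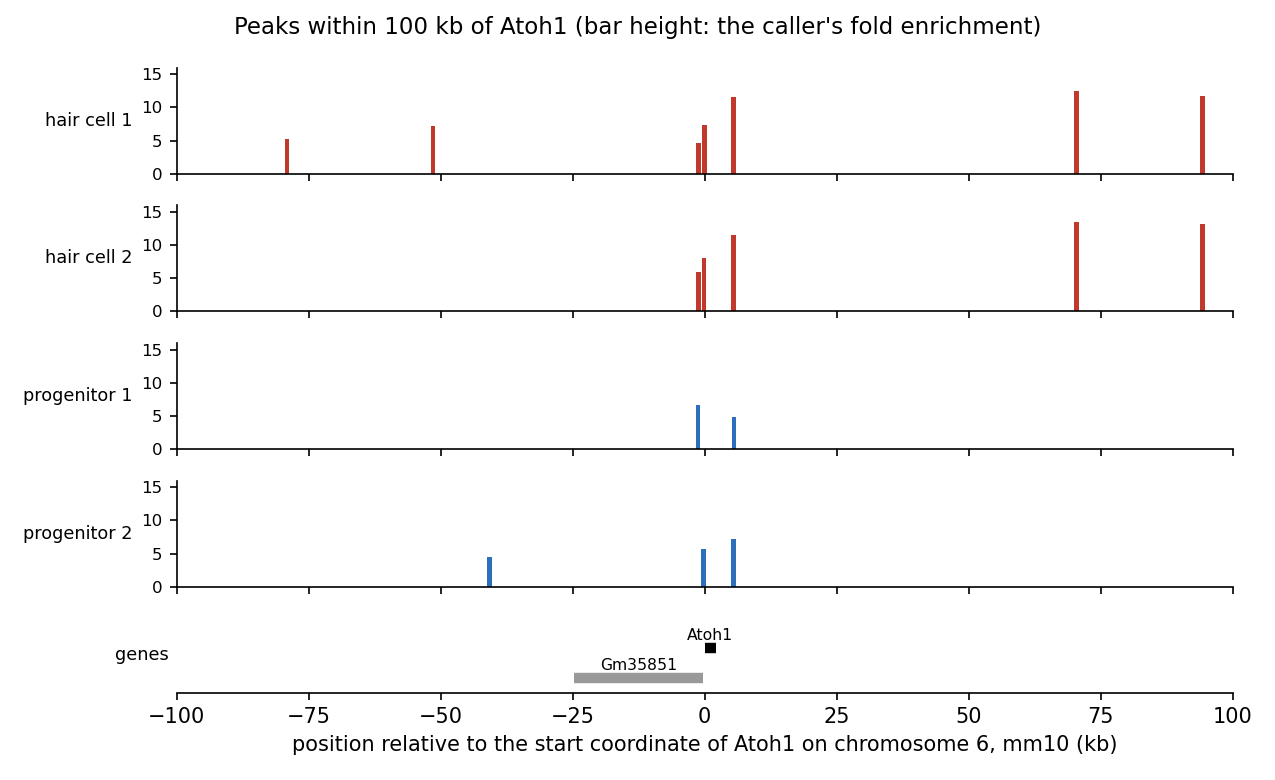
Peaks of the 4 libraries within 100 kb of the start coordinate of Atoh1 (horizontal axis in kb, mm10). The height of each bar is the caller's fold enrichment, bars are drawn at least 0.9 kb wide to be visible, and the lowest panel shows Atoh1 and Gm35851. The peaks at 70.5 and 94.3 kb appear in both hair cell libraries only, and the peak at 5.43 kb appears in all 4.

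Shared regions sat mostly at gene ends, hair cell-specific regions less often, and progenitor-specific regions seldom. A gene end here is the stretch 1 kb either side of the start or end coordinate of a protein-coding gene, since the annotation used gave no strand and promoters could not be told from gene 3' ends. It held 72.5% of the regions open in all 4 libraries (95% exact binomial interval 71.2% to 73.7%, n = 5048), 18.4% of the hair cell-specific regions (17.8% to 19.1%, n = 14952) and 4.62% of the progenitor-specific regions (4.02% to 5.29%, n = 4346). After a shift of 50 kb the same classes gave 9.25%, 6.27% and 4.05%. Progenitor-specific regions lay over 100 kb from any protein-coding gene in 20.6% of cases and hair cell-specific regions in 8.73%. Gene bodies held 50.4% and 63.0% of them. Hair cell-specific and progenitor-specific regions differed in all 3 shares by Fisher's exact test, two-sided, adjusted over 12 comparisons of classes (adjusted p = 3.7e-134 for gene ends, 9.9e-92 for the distance over 100 kb and 6.9e-50 for gene bodies). Regions are not replicate samples, so the test compares these lists and the intervals cover counting error only. With the same number of peaks from every list the share at gene ends was 9.06% of the progenitor-specific regions (8.25% to 9.94%, n = 4556) and 20.7% of the hair cell-specific ones (19.7% to 21.8%, n = 5884). With 1 height over background asked of both classes the shares were 4.52% and 18.7%.

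Counting regions gene by gene, 8532 of 21887 protein-coding genes had at least 1 group-specific region; 6940 had more hair cell-specific ones, 1010 more progenitor-specific ones and 582 as many of both. The largest excess for hair cells was at Ctnnd2, which encodes delta-catenin (chromosome 15, 30172534 to 31029344), with 18 hair cell-specific regions and 1 progenitor-specific region. Gse1 followed with 17 and 2, Camta1, a calmodulin-binding transcription activator, with 15 and 1, and the teneurin gene Tenm4 with 18 and 6. Snd1 had 14 and 2, Aff3 14 and 3, and Arid1b, a subunit of BAF chromatin remodelers, 12 and 1. Lrmda and Ptprn2 had 11 hair cell-specific regions and 0 progenitor-specific ones, Foxp1, a forkhead transcription factor, and Smyd3 had 11 and 1, and Ldlrad3 had 10 and 0. Of these hair cell-specific regions, 4 at Ctnnd2, 9 at Gse1, 8 at Tenm4, 2 at Aff3 and 0 at Ptprn2 were high enough for the progenitor depth. The hair cell share at Ctnnd2 was 94.7% (exact binomial interval 74.0% to 99.9%), which takes in the 77.5% of all group-specific regions. Regions inside a gene body count for that gene, and gene length was not taken into account in either ranking, so long genes can lead for that reason. Assigned to the nearest end of any gene, the excess at Ctnnd2 was 6 in place of 17, and 28 genes had a larger one. Leaving out hair cell replicate 1 put 2 genes ahead of Ctnnd2, and leaving out replicate 2 put 1 ahead.

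The largest excess for progenitors was at Reln, which encodes the secreted protein reelin (chromosome 5, 21884454 to 22344705), with 7 progenitor-specific regions and 1 hair cell-specific region. Dlgap2, a postsynaptic scaffold gene, had 7 and 2, Ralgps1 6 and 1, and Dab1, the intracellular adaptor of reelin signaling, 8 and 4. The phospholipase gene Plcb1 and Ppp1r14c had 5 and 0. Clstn2, the neuronal zinc finger gene Myt1l, Fam53b, Chst15 and Hivep3 had 5 and 1, and Lrrc55 had 4 and 0. The hair cell share at Reln was 12.5% (exact binomial interval 0.316% to 52.7%), below the 77.5% of all group-specific regions, although genes were ranked on this very excess. Both rested on hair cell replicate 2: without it Reln had 5 hair cell-specific against 7 progenitor-specific regions, a share of 41.7%, and 40 genes had a larger progenitor excess.

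Genes of the hair bundle, mechanotransduction and the ribbon synapse carried an excess of hair cell-specific regions. The 40 genes of this list had 131 hair cell-specific and 11 progenitor-specific regions, 92.3% (exact binomial interval 86.6% to 96.1%), and 35 of the genes had more of the former. The tip-link cadherin genes Pcdh15 and Cdh23 had 7 hair cell-specific and 0 progenitor-specific regions and 7 and 1, and Eps8, an actin regulator of stereocilia, had 7 and 0. The list exceeded random lists matched on their number of group-specific regions by 1.10 regions per gene (permutation test, two-sided, adjusted p = 0.0039 over 20 lists). Without granule neuron progenitor replicate 1 it had 131 and 38 regions, 77.5%, and exceeded matched lists by 1.81. Over all regions that setting gave 15851 hair cell-specific and 11631 progenitor-specific ones, so the hair cell share fell in general. With only peaks of -log10 q of at least 5 the adjusted p was 0.097, the highest of a range from 2e-04 over all alternatives. At their ends, 28 and 29 of the 40 genes had a merged region with a peak in hair cell replicates 1 and 2. In progenitor replicates 1 and 2 these were 3 and 6. Such a region, here called a gene-end peak, can reach the gene end through the peak of another library. Over all protein-coding genes these shares were 48.6% and 50.6% in hair cells and 25.7% and 35.7% in progenitors.

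Hair cell transcription factor genes had 32 hair cell-specific regions and 1 progenitor-specific region, and 11 of the 14 genes had more of the former. Pou4f3, a POU-domain factor needed for hair cell survival (chromosome 18, 42394597 to 42396093), had 5 and 0. Sox4, a SOX-family factor, and Zfp503, a zinc finger factor, had 4 and 0 each. As a list these genes did not pass the matched test with the peaks as listed (permutation test, adjusted p = 0.113). They passed it among regions high enough for the other group's depth, with 13 regions against 1 (permutation test, adjusted p = 0.0201), and with equal numbers of peaks per list (adjusted p = 0.0399, same permutation test). Over all alternatives the adjusted p of this list ran from 0.0013 to 0.236.

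Granule neuron progenitor genes had a smaller excess of hair cell-specific regions than matched genes. The 26 transcription factor and marker genes of this list had 39 hair cell-specific and 33 progenitor-specific regions, 54.2% (exact binomial interval 42.0% to 66.0%). Their mean excess of hair cell-specific regions was 0.231 per gene, against 1.51 in matched random lists (difference -1.28, permutation test, two-sided, adjusted p = 0.0020 over 20 lists). The majority turned without granule neuron progenitor replicate 1 (40 hair cell-specific and 68 progenitor-specific regions, 37.0%) and without replicate 2 (43 and 52, 45.3%). Over all regions, leaving out replicate 1 gave 15851 hair cell-specific and 11631 progenitor-specific ones. With all 4 libraries, 12 of the genes had more progenitor-specific regions and 10 more hair cell-specific ones. Pax6, a paired-box factor of these progenitors, had 4 progenitor-specific and 2 hair cell-specific regions. Nuclear factor Nfia had 7 and 10, the semaphorin gene Sema6a 2 and 6, and the homeobox gene Meis2 0 and 4. A gene-end peak was present at 12 and 19 of the genes in progenitor replicates 1 and 2, and at 7 and 11 in hair cell replicates 1 and 2. The call of the list was lost among regions high enough for the other group's depth (13 hair cell-specific against 33 progenitor-specific, adjusted permutation p = 0.0835) and with random lists not matched on region number (adjusted p = 0.544), and over all alternatives it ran from 0.0012 to 0.544.

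Genes of maturing granule neurons had 31 hair cell-specific and 27 progenitor-specific regions over 19 genes, -1.39 regions per gene relative to matched lists (permutation test, two-sided, adjusted p = 0.00807). Leaving out granule neuron progenitor replicate 1 gave 31 and 49 regions, a hair cell share of 38.8%, so the majority turned. Over all regions the same setting gave 15851 hair cell-specific and 11631 progenitor-specific ones. Of the 27 progenitor-specific regions with all 4 libraries, Reln held 7. The metabotropic glutamate receptor gene Grm4 had 3 progenitor-specific and 7 hair cell-specific regions, the phosphodiesterase gene Pde1c 3 and 5, and the cadherin gene Fat2 3 and 1. The adjusted p was 0.0532 with equal numbers of peaks per list, 0.0562 without hair cell replicate 2, 0.13 without granule neuron progenitor replicate 1 and 0.197 among regions high enough for the other group's depth, within a range of 0.0027 to 0.553 over all alternatives.

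**Figure D3:**
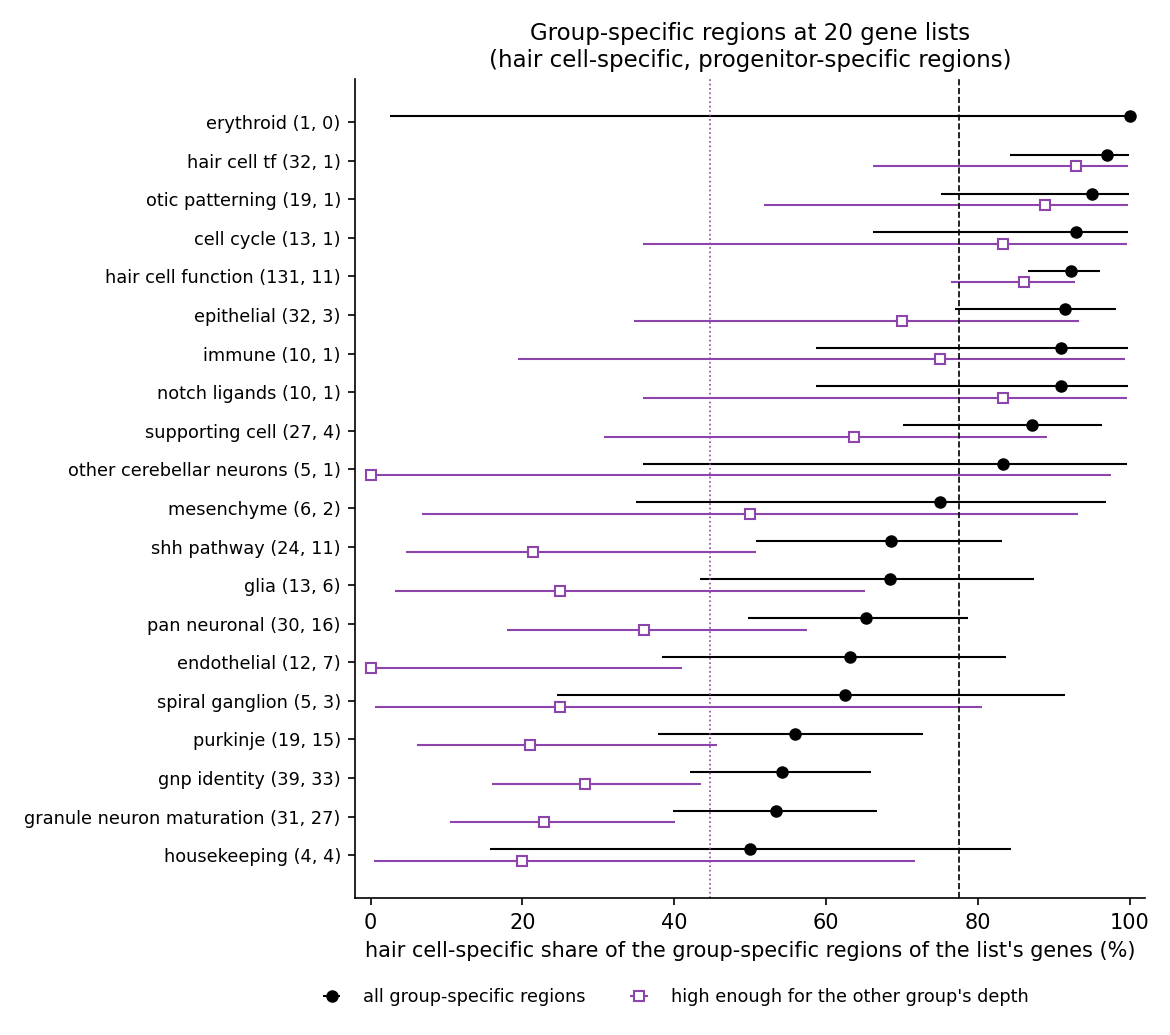
Hair cell-specific share (horizontal axis, percent) of the group-specific regions assigned to the genes of each of the 20 lists, with the numbers of hair cell-specific and progenitor-specific regions beside each name. Filled circles use all group-specific regions and open squares those high enough for the other group's depth, bars are 95% exact binomial intervals, and the dashed and dotted lines mark the share over all genes for circles and squares. Hair cell function genes lie at 92.3% and 86.1%, and granule neuron progenitor identity genes at 54.2% and 28.3%.

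None of the other 16 lists passed the matched permutation test with the peaks as listed (two-sided, adjusted over 20 lists). Among cochlear lists, Notch ligand genes had 10 hair cell-specific and 1 progenitor-specific regions (adjusted permutation p = 0.646), led by Dll1 with 4 and 0 and Jag2 with 3 and 0. Otic patterning genes had 19 and 1 (adjusted permutation p = 0.303), with Eya4 at 6 and 0 and Pax2 at 3 and 0. Epithelial genes had 32 and 3 (adjusted permutation p = 0.38), with Grhl1, Cdh1 and Cldn4 at 3 and 0. A gene-end peak was present at 13 and 18 of the 24 genes in hair cells (54.2% and 75.0%). In progenitors it was present at 2 and 3 (8.33% and 12.5%). Over all protein-coding genes the shares were 48.6% and 50.6% in hair cells and 25.7% and 35.7% in progenitors. Supporting cell genes, which mark the neighbours of hair cells, had 27 and 4 (adjusted permutation p = 0.646), with Slc1a3 at 4 and 1. This split narrowed to 27 and 19 without granule neuron progenitor replicate 1, and to 9 and 7 with equal numbers of peaks per list. All regions narrowed too, to 15851 and 11631 in the former setting and to 5884 and 4556 in the latter. Spiral ganglion genes had 5 and 3 (adjusted permutation p = 0.646).

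Among cerebellar lists, Sonic hedgehog pathway genes had 24 hair cell-specific and 11 progenitor-specific regions (adjusted permutation p = 0.449), with Gli2 at 6 and 4 and Gas1 at 4 and 1. Purkinje cell genes had 19 and 15 (adjusted permutation p = 0.0635), with the LIM-homeobox gene Lhx1 at 0 and 4, Dab1 at 4 and 8 and Rora at 5 and 0. Genes of other cerebellar neurons had 5 and 1 (adjusted permutation p = 1), glial genes 13 and 6 (adjusted permutation p = 0.458) and pan-neuronal genes 30 and 16 (adjusted permutation p = 0.303). Nefm, a neurofilament gene of the last list, had 4 hair cell-specific regions and 0 progenitor-specific ones.

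Lists for cells that a sort could carry along were small. Immune genes had 10 hair cell-specific and 1 progenitor-specific regions (adjusted permutation p = 0.646), with Laptm5 at 4 and 1 and C1qb at 2 and 0. A gene-end peak was present at 2 of 11 immune genes in each hair cell library and at 0 in each progenitor library. The 11 endothelial genes gave the same gene-end counts. Endothelial genes had 12 hair cell-specific and 7 progenitor-specific regions (adjusted permutation p = 0.41), with Flt1 at 5 and 1. Among regions high enough for the other group's depth they had 0 and 7 (adjusted permutation p = 0.0447, range over alternatives 0.0447 to 1). Erythroid genes had 1 and 0 (adjusted permutation p = 1) and mesenchymal genes 6 and 2 (adjusted permutation p = 1), of which Otos, a gene of cochlear fibrocytes, held 4 and 0. Cell cycle genes had 13 and 1 (adjusted permutation p = 0.574), with Mcm6, Cdc6 and Plk1 at 2 and 0, and housekeeping genes had 4 and 4 (adjusted permutation p = 0.175). Gene-end peaks were commoner in hair cells at these lists too. They were present at 16 and 19 of 21 cell cycle genes, against 10 and 12 in progenitors. For the 20 housekeeping genes the counts were 17 and 15 against 9 and 12.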

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

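Of the tests in this part, the count of progenitor peaks outside chromosomes 1 to 19 and X and the chances from regions outside gene ends were chosen after the result was seen. Hair cell replicate 1 had 14 peaks and hair cell replicate 2 had 10 on unplaced scaffolds and patches, sequences that no comparison used, while both progenitor lists had 0 there. These values stand out because they lie above the 3 that a count of 0 allows.

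On those sequences and chromosome Y, 11 regions had a peak in both hair cell libraries, 2 of them on Y, and none had a progenitor peak. Judged from hair cell regions of similar height on chromosomes 1 to 19 and X the chance of none was 1.78e-04 (7.82e-04 for the 9 regions off chromosome Y), but this planned test pooled gene ends with other regions, and progenitor peaks were commoner at gene ends. From regions outside gene ends alone the chance was 0.0326, and 0.0565 with 1 region for each of the 8 sequences, since neighbours are not independent, so the depth of the libraries stays open. An alignment index or filter that differed between the groups may be the cause; the progenitor lists held 0 peaks outside chromosomes 1 to 19 and X, but such a step cannot be told apart from the groups, since it would follow them exactly. The sex of the animals and a difference between the tissues stay open and were not tested.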

How the results depend on the processing

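Assignment to the nearest end of any gene, 1 height over background asked of both classes, the use of high-enough regions for lists, gene ends and Aff3, the Jaccard index of regions, libraries left out of the agreement test, counts of genes with a larger excess than Reln or Ctnnd2, shares in gene bodies and beyond 100 kb, and all alternatives at the Atoh1 locus were chosen after seeing the data. No paired analysis was possible because the labels give hair cell and progenitor replicates only the same numbers, with no shared animal, litter or day, and the counts of specific regions come from no test. Motif alternatives were not run, and the nearest transcription start site could not be used.

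The excess of shared bases within groups over between groups kept its sign in all 10 alternatives (0.156 to 0.391). The differences between hair cell-specific and progenitor-specific regions at gene ends (10.7 to 20.7 percentage points), in gene bodies and over 100 kb from a gene kept their direction and passed Fisher's test in all alternatives run. Region counts did not hold. With -log10 q of at least 5 there were 2490 progenitor-specific and 3241 shared regions and a ratio of 5.77. With equal numbers of peaks per list there were 5884 hair cell-specific regions and a ratio of 1.29, and gene ends held 9.06% of the progenitor-specific regions in place of 4.62%. Only 3517 hair cell-specific regions were high enough for the progenitor depth, which turned the ratio to 0.809. All 4346 progenitor-specific regions pass that filter by construction, so it could only lower the ratio. With 1 height over background asked of both classes 3517 and 3961 regions remained, and the ratio was turned to 0.888. This cut, set by progenitor replicate 1, also fell mostly on hair cell-specific regions. Without 1 library in turn there were 15851 to 24812 hair cell-specific, 4611 to 11631 progenitor-specific and 5273 to 8083 shared regions, ratios of 1.36 to 5.38 and 2 to 4 hair cell-specific regions at Atoh1. Dropping a library loosens the definition, which raises these counts.

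Of 220 list results under alternatives, 204 stayed on their side of the threshold; 13 of these, in 8 lists that passed in neither setting, changed sign. Values are regions per gene relative to random lists. With -log10 q of at least 5, hair cell function fell out of the calls at 0.563 (adjusted permutation p = 0.097, range over alternatives 2e-04 to 0.097) and Purkinje genes entered at -1.14. With equal numbers of peaks, hair cell transcription factors entered at 0.791 and granule neuron maturation fell out at -0.870. Among high-enough regions, hair cell transcription factors entered at 0.873 and endothelial genes at -0.666, while progenitor identity (-0.720) and granule neuron maturation (-0.728) fell out. With unmatched random lists, hair cell transcription factors (1.75) and epithelial genes (0.743) entered, and progenitor identity (-0.234) and granule neuron maturation (-0.257) fell out. Without 1 library in turn, hair cell function ranged from 0.888 to 1.81 and passed each time, hair cell transcription factors ranged from 0.771 to 1.56 and passed without either progenitor library, and granule neuron maturation ranged from -1.58 to -1.25 and failed without hair cell replicate 2 or progenitor replicate 1. Of 911 results for 97 named genes, 841 lay within the exact interval of the listed value, which is wide for few regions, and 70 outside it; in 59 further cases no group-specific region was left. The share crossed 50% in 35 results of 19 genes, for example from 70% to 0% at Grm4 and from 100% to 0% at Rora with equal numbers of peaks, and from 16.7% to 100% at Chst15 with -log10 q of at least 5. Of the 15 genes whose listed interval excluded 50%, only Aff3 crossed it, at 40% among high-enough regions. A crossing can follow a shift of all regions. Hair cell-specific against progenitor-specific regions numbered 14952 and 4346 as listed, 3517 and 4346 among high-enough regions, and 5884 and 4556 with equal numbers of peaks. No gene had a larger excess than Ctnnd2 as listed, but 26 did among high-enough regions and 28 with the nearest end of any gene. The cause of these list and gene changes was not tested.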

Other observations

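Of the tests in this part, 3 were chosen after results were seen: the comparison of found regions outside with those at gene ends, the ratio with 1 height over background asked of both classes, and the shares at gene ends with equal numbers of peaks. The second replaced a planned ratio (0.809) whose filter could remove hair cell-specific regions only. Gene-end regions were common to both cell types far more than other regions. Of the 4013 gene-end regions in both progenitor libraries 5.01% lacked a peak in both hair cell libraries, against 68.7% of the 6032 other regions. In the opposite direction 69.3% of 8974 gene-end regions in both hair cell libraries had a progenitor peak, against 18.5% of 14960 other regions. Several neuronal genes, named after their values were seen, had group-specific regions in progenitors only: Gap43 had 3, and Stmn2, Elavl3 and the proneural gene Neurod1 had 2 each, with 0 hair cell-specific regions. The zinc finger genes Zic1, Zic2, Zic4 and Zic5, markers of granule neuron progenitors, had 1 progenitor-specific region each and 0 hair cell-specific ones. In hair cells, the motor gene Myo6 had 6 hair cell-specific regions and 0 progenitor-specific ones, and Espn, Ptprq and Clrn1 had 5 and 0.

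The progenitor lists were shorter, agreed less with each other and gave fewer specific regions, and the depth of the libraries is a candidate explanation for each. With 1 height over background asked of both classes, which kept 23.5% of hair cell-specific and 91.1% of progenitor-specific regions, their ratio was 0.888, no longer above 1, and hair cell lists thinned to the progenitor background differed from the progenitor lists in their Jaccard index of regions by only -0.0135, at a mean of 0.378 against 0.392 (0.580 before thinning). Depth as the whole cause of hair cell regions without a progenitor peak was left undecided at matched height. There, regions of hair cell replicate 1 were found 1.28 and 1.23 times as often as regions of the other progenitor library. For hair cell replicate 2 these values were 0.818 and 0.835. Why the hair cell libraries differed was not tested. The ratio of found to expected regions was, however, only 0.458 to 0.624 times as high outside gene ends as at gene ends in the 4 pairs. This argues against depth as the whole cause there only as far as a wrong scaling moves both alike. From hair cell replicate 1 to 2 this relative value fell from 0.508 to 0.458 in progenitor replicate 1. In progenitor replicate 2 it fell from 0.624 to 0.505, so the 2 kinds of region did not move quite alike. A difference between the cell types, tissues or ages stays open for those regions. Thinning the hair cell peaks to the progenitor background left a mean of 4870 regions uncalled in both progenitor libraries, 0.326 times the 14952 observed. Between replicates, however, it gave only 0.215 times the regions of hair cell replicate 1 missing in replicate 2. From progenitor replicate 2 to 1 this value was 0.274. Thinning thus missed most losses even within a group, so this planned test could not settle the question. The thinned Jaccard index above carries the same limit.

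Progenitor-specific regions seldom lay at gene ends, at 4.62% against 18.4% of hair cell-specific ones. Of 4 equal groups by strength the strongest had 0.395 times the share at gene ends of the weakest (2.94% against 7.45%), but hair cell-specific regions fell likewise (0.608 times), as the removal of strong shared gene ends would give in either class, so the planned reading against weak background peaks does not hold. With equal numbers of peaks the progenitor share rose to 9.06% against 20.7%, and the ratio of the shares from 0.251 to 0.438. That setting keeps the peaks with the highest -log10 p, so it changes list length and peak strength at once. Peaks of -log10 q of at least 5 gave 3.86% against 24.4%. How much of the gap came from list length was not separated. The gap that remained argues against list length as the whole cause (Fisher's exact test p = 3.6e-62). Regions are not replicate samples, so this p covers counting error in these lists only and not the spread between libraries. Weak background peaks, depth beyond list length, gaps in the annotation and a difference between the cell types all stay open for the rest.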
